A study of Mus musculus with 14 samples.

How the data were processed

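Bone marrow cells from mice with and without breast tumours were profiled in 14 samples: 8 bulk RNA libraries of mesenchymal stem cells (MSC), 2 single-cell libraries of marrow stromal cells and 4 single-cell libraries of hematopoietic stem and progenitor cells (HSPC). Per the labels, bulk libraries were made from total RNA with a strand-specific kit for very small inputs, and single cells were captured with droplet 3' chemistry. The labels name v3.1 of that chemistry in one place and v2 or v3 in another. Per the submitters' processing notes, Trim Galore (no version given), STAR 2.5.3a and Cell Ranger 6.0.0 were used with the mouse build mm10. The read counter, its strand setting and the annotation behind the bulk table are not given in the sources used here, nor are the gates of the sorts.

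The deposited bulk table holds raw read counts per Ensembl gene, per the file headers and the whole-number values, for 50600 genes and 8 libraries. The deposited single-cell tables hold raw counts of unique molecular identifiers (UMIs) per gene and cell, which equal the totals in the authors' cell metadata. The deposited stromal metadata give the mitochondrial share of each cell as a fraction and a cluster number, whose header names a clustering of integrated data. The deposited HSPC metadata give the mitochondrial share as a percent, the genotype and the mouse of each cell. No HSPC cell lies above 4.50% mitochondrial UMIs, so cells had been filtered before deposit by rules not given in the sources used here. The authors' cell cycle calls were not used here.

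Bulk groups were taken from the sample titles, and the genotype labels match: 4 tumour-free and 4 Py230 tumour-bearing libraries. Single-cell groups were taken from the genotype labels: 1 wild-type (WT) and 1 PyMT stromal library, and 2 WT and 2 PyMT HSPC libraries. The labels do not say that the bulk libraries came from separate animals, so their p-values measure only the spread between these libraries, which may be technical. The HSPC metadata name a separate mouse for each library. The titles and mouse names of all 4 HSPC libraries carry a PyMT prefix, whereas the genotype labels and the condition column of the metadata give WT for 2 of them; the genotype was used.

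Bulk counts were tested with edgeR 4.0.16 (R 4.3.3; TMM factors, filterByExpr, robust quasi-likelihood fit, Benjamini-Hochberg adjustment, threshold 0.05). Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over all lists with at least 5 tested members, and again with the correlation estimated per list. Adjusted p-values given for genes come from edgeR and those for lists from camera unless another tool is named. CPM values of single genes in the bulk libraries are TMM-normalised, except that those of Ptprc and the sums of marker genes are plain CPM of counted reads. Sums of marker genes per library were compared by exact permutation (35 splits of the 8 libraries; smallest p 0.0286). The test was checked on simulated counts for 16010 genes: it recovered 6.0% of 1.5-fold, 59.7% of 2-fold and 100% of 4-fold changes, and 3.5% of its calls were false.

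Stromal cells with at least 500 genes and under 10% mitochondrial UMIs were kept, 2190 of 2508 WT and 3191 of 3563 PyMT cells. The plan was to cluster both libraries jointly unless cell types had been deposited. Joint clustering split the main population by library, so the authors' 6 numbered clusters were used instead, a choice made after seeing the data. Clusters were named from markers chosen in advance. Scrublet marked 1.36% of WT and 0.11% of PyMT cells as doublets, which were left in. With 1 library per genotype no test between genotypes was made. UMIs were summed per cluster with at least 100 cells in each library, log2 ratios of CPM were taken with 95% exact Poisson intervals, and cluster shares were given with 95% Clopper-Pearson intervals. These intervals cover counting error only. The median of each gene list (members with at least 20 UMIs) was placed among those of 10000 random lists matched on expression, and called outside where it lay in the lowest or highest 2.5%. On simulated counts, 96.0% of intervals held the true ratio and 1 of 20 unchanged lists fell in the tails. Those counts varied by counting error only, and each gene on its own. The simulation therefore checks the calculation and gives no rate of false calls for real lists.

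HSPC cells were clustered here (scanpy 1.11.5, leidenalg 0.10.2; 2000 variable genes, 30 components, 20 neighbours, resolution 0.6) and named by markers chosen in advance. Scrublet marked 13 of 14842 cells (0.088%), too few for the caller to have worked, so doublets remain an open source of mixed profiles. UMIs were summed per library over all cells, and within each cluster with at least 50 cells in every library, and tested as for the bulk. Shares were compared by exact two-sided permutation, whose 3 splits allow no p below 0.333, and cell numbers per cluster also with edgeR. On simulated sums of 11728 genes the test recovered 44.8% of 1.5-fold and 89.6% of 2-fold changes, with 5.5% of calls false.

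The genes named are, per comparison and direction, the 8 with the smallest p and separate CPM ranges at a mean of at least 5 CPM (5 by ratio in stromal clusters; 3 in HSPC clusters), up to 4 members of each list described, and a set of niche and lineage genes. Rules, lists, markers and most alternatives were chosen before the data were examined. Alternatives were other size factors, no filter on low counts, limma-voom with quality weights, DESeq2 1.42.0, a replicate block, the estimated correlation, fry, leaving out each library, other cell filters and clusterings, doublets left out, per-cell means and thinned UMIs. Gene positions are from GENCODE on GRCm38; 50376 of the 50600 bulk identifiers were in it. Numbers came from numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 on Python 3.11.15.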

Results

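The data cover mesenchymal stem cells (MSC), stromal cells and blood-forming progenitors from the bone marrow of mice with or without a breast tumour. MSC were profiled in bulk from 4 tumour-free samples and 4 samples from mice bearing Py230 tumours. Py230 is a mammary tumour line that was derived from a PyMT mouse, a strain in which the polyoma middle T oncogene drives mammary tumours. The bulk libraries held 4301375 to 9811251 counted reads. Stromal cells were profiled one by one in 1 wild-type (WT) and 1 PyMT library, with 10730286 and 16231829 UMIs. Hematopoietic stem and progenitor cells (HSPC) came from 2 WT mice (3422 and 2210 cells) and 2 PyMT mice (3602 and 5608 cells), with 16365550 to 28570481 UMIs per mouse. The genotypes are those of the labels; the titles of all 4 HSPC libraries carry a PyMT prefix. The comparisons ask how each population differs when a tumour grows elsewhere in the body, and, for HSPC, whether the balance of myeloid and lymphoid progenitors differs.

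MSC of mice with Py230 tumours held less RNA of many of the factors by which marrow stroma maintains hematopoietic stem cells (HSC). Cxcl12, the chemokine that retains HSC in the marrow, fell from 20064 ± 1499 to 10375 ± 1591 CPM (SD, n = 4 per group; log2 change −0.95, SE 0.13, adjusted p = 0.0012). Bmp4, a bone morphogenetic protein, fell 4.35-fold, from 187 ± 31.3 to 42.9 ± 10.2 CPM (log2 change −2.12, SE 0.17, adjusted p = 4.29e-05). The growth factor Igf1 fell 3.29-fold, the lymphoid cytokine Il7 2.79-fold and the Tie2 ligand Angpt1 2.17-fold. The macrophage growth factor Csf1 fell from 728 ± 36.8 to 385 ± 78.2 CPM and the adhesion molecule Vcam1 from 1359 ± 181 to 749 ± 60.5 CPM. Transcripts of Kitl, the ligand of the stem cell receptor Kit, were at 1594 ± 111 and 1406 ± 93.7 CPM (adjusted p = 0.417), and those of the leptin receptor Lepr at 3409 ± 349 and 2947 ± 166 CPM (adjusted p = 0.368). Spp1 (osteopontin) did not pass the test either (181 ± 56.7 and 230.1 ± 52.9 CPM, adjusted p = 0.551).

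Of the 27 HSC niche factors tested, 14 fell and 1, Vegfa, rose over all genes, and 16 fell and 1 rose when adjusted over the list alone. Their median log2 change was −0.72 (camera, adjusted p = 2.26e-24), and the call held at adjusted p = 0.023 with an estimated correlation, the only one of 13 called lists to do so. In GRCm38, Cxcl12 (ENSMUSG00000061353) lies on chromosome 6 from 117168535 to 117181367 on the plus strand, Bmp4 (ENSMUSG00000021835) on chromosome 14 from 46383520 to 46390669 on the minus strand, Kitl on chromosome 10 from 100015630 to 100100416 and Lepr on chromosome 4 from 101717404 to 101815352, both on the plus strand. All 4 are protein-coding genes, and the counts are over whole genes.

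**Figure D1:**
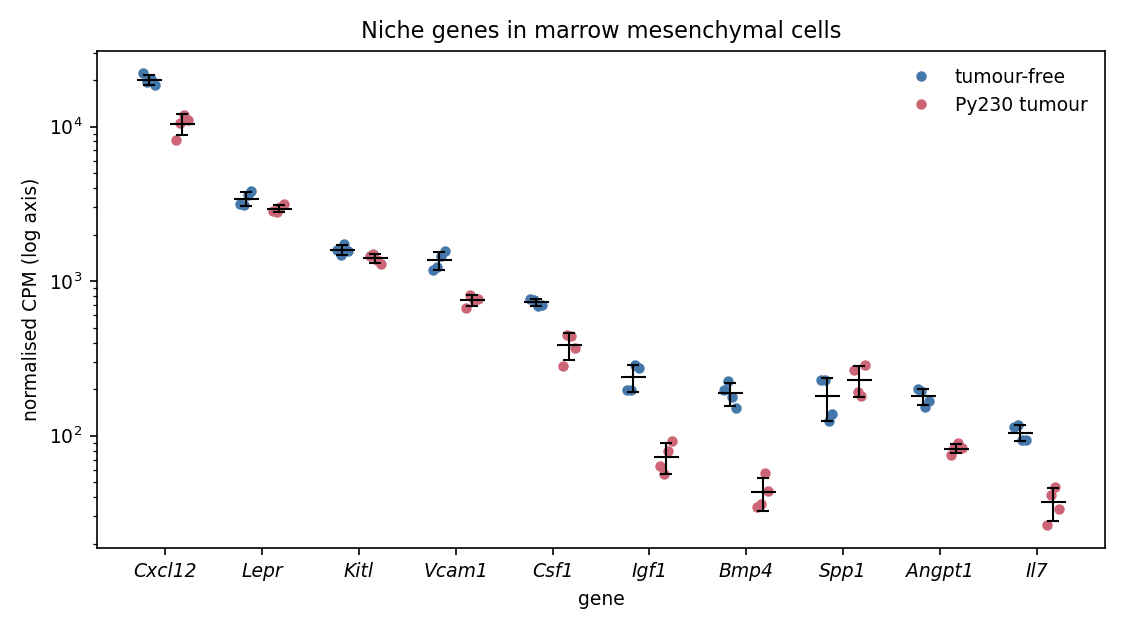
Normalised CPM (log axis) of 10 niche genes in each bulk MSC library, tumour-free in blue and Py230 tumour in red; horizontal bars and whiskers give the mean ± SD of 4 libraries. Cxcl12, Vcam1, Csf1, Igf1, Bmp4, Angpt1 and Il7 lay lower in every tumour library, whereas Lepr, Kitl and Spp1 overlapped.

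Genes of the adipocyte lineage and of LepR+ stromal identity also fell, but these lists overlap and are not separate results. The identity list shares Cxcl12, Kitl, Esm1 and Gas6 with the niche factors. It shares Adipoq, Lpl and Apoe with the adipocyte genes. Lipoprotein lipase (Lpl) went from 2009 ± 39.1 to 753 ± 113 CPM (log2 change −1.41, SE 0.12, adjusted p = 4.29e-05), the adipokine gene Adipoq from 663 ± 93.8 to 202 ± 62.9 CPM (log2 change −1.71, SE 0.22, adjusted p = 0.0014) and Chrdl1, a secreted BMP antagonist, fell 3.62-fold. Of 20 adipocyte genes 7 fell (8 adjusted over the list alone; median log2 change −0.45, adjusted p = 3.23e-07, adjusted p = 0.103 with an estimated correlation). Of 24 LepR+ identity genes 8 fell (11 lower and 2 higher adjusted over the list alone; median −0.33, adjusted p = 8.58e-11, adjusted p = 0.061 with an estimated correlation). The smallest p among lower genes was that of the anion transporter Slc26a7 (133.8 ± 20.6 to 35.7 ± 2.44 CPM). Others with small p were the potassium-dependent sodium-calcium exchanger Slc24a3 (2.98-fold), Cd93, Ehd3, Nnmt and Adamtsl3 (2.32-fold to 2.84-fold).

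Among genes that rose, the matrix metalloprotease Mmp11 went from 27.0 ± 2.02 to 71.0 ± 7.63 CPM (log2 change 1.40, SE 0.11, adjusted p = 4.29e-05), with 1 tumour-free library at 24.0 CPM apart from the other three. The CCN family member Wisp2 rose 2.92-fold, the proteoglycan decorin (Dcn) 2.15-fold, the integrin subunit Itgb5 1.97-fold and the transcription factor Bhlhe40 went from 157 ± 26.2 to 314 ± 18.3 CPM. Rgs20, Adra2a and Cbfa2t3 rose 2.79-fold, 2.88-fold and 2.27-fold. The oncostatin M receptor Osmr rose from 293 ± 39.9 to 566 ± 72.4 CPM and the secreted glycoprotein Lrg1 from 2.28 ± 0.528 to 13.6 ± 6.29 CPM. The 24 acute-phase and STAT3 target genes moved both ways, with 5 higher, Osmr, Lrg1 and Il1r1 among them, and 6 lower, including the feedback inhibitor Socs1 (2.14-fold); the counts were the same adjusted over the list alone, and the list was not called (median 0.01, adjusted p = 0.861).

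Hypoxia and glycolysis genes rose as a list (6 of 30 higher, 12 higher and 1 lower adjusted over the list alone; median 0.28, adjusted p = 3.82e-06, adjusted p = 0.428 with an estimated correlation), with Vegfa at 1.85-fold, Ddit4 at 2.13-fold and P4ha1 at 1.52-fold. Cholesterol synthesis genes fell (4 of 22, 13 adjusted over the list alone; median −0.49, adjusted p = 7.00e-10, adjusted p = 0.419 with an estimated correlation), with the sterol demethylase Cyp51 down from 29.6 ± 4.10 to 12.6 ± 3.63 CPM and Hsd17b7 1.74-fold lower. Oxidative phosphorylation genes were called lower (median −0.24, adjusted p = 6.16e-05, adjusted p = 0.695 with an estimated correlation), although 1 of 47 passed the test over all genes and over the list alone, Cox5a. The call of Cox5a was lost without tumour-free replicates 1, 2 and 4 (adjusted p = 0.113, 0.0522 and 0.0663) and without Py230 replicates 1 and 2 (0.0607 and 0.101).

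Interferon response genes were called lower (median −0.22, adjusted p = 1.78e-04, adjusted p = 0.696 with an estimated correlation), with 4 of 37 lower over all genes and adjusted over the list alone. These were the GTPases Irgm1, Iigp1 and Ifi47 and the chemokine Cxcl10, and each call was lost without some libraries. Without tumour-free replicate 1 the adjusted p-values of Irgm1, Cxcl10, Iigp1 and Ifi47 were 0.0521, 0.112, 0.122 and 0.173, and without Py230 replicate 3 they were 0.0517, 0.123, 0.0941 and 0.145. Cxcl10, Iigp1 and Ifi47 were also lost without tumour-free replicate 2 (0.0966, 0.0858 and 0.051), tumour-free replicate 3 (0.0827, 0.0839 and 0.083) or Py230 replicate 4 (0.095, 0.106 and 0.128), and Ifi47 without Py230 replicate 1 (0.135).

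The calls of 5 other lists depended on single libraries, and none held with an estimated correlation (adjusted p = 0.428 to 0.72). Osteolineage genes were lower (2 of 22, Phex and Omd; 3 lower and 1 higher adjusted over the list alone; adjusted p = 0.0361) but not without tumour-free replicate 1 (0.152), tumour-free replicate 3 (0.0599) or Py230 replicate 1 (0.394). NF-kB and cytokine genes were lower (1 of 32 higher and 6 lower, 5 and 7 adjusted over the list alone; adjusted p = 0.0107), with Irf1 at 2.44-fold lower, but not without tumour-free replicate 3 (0.0879) or Py230 replicate 1 (0.0549). Mitochondrially encoded transcripts were lower (0 of 11 passed edgeR's test, and 4 had an unadjusted p under 0.05; adjusted p = 0.0104) but not without tumour-free replicate 1 (0.152). Fibroblast genes were higher (3 of 17 higher and 2 lower, 8 and 2 adjusted over the list alone; adjusted p = 0.00943) but not without tumour-free replicate 4 (0.0715), Py230 replicate 3 (0.123) or Py230 replicate 4 (0.0528). Pericyte and smooth muscle markers were higher (1 of 12, 3 adjusted over the list alone; adjusted p = 0.0412) but not without tumour-free replicate 2 (0.108), tumour-free replicate 3 (0.0599), Py230 replicate 3 (0.123) or Py230 replicate 4 (0.106).

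Markers of other cell types moved in different directions. Arterial endothelial markers were higher as a list (2 of 11, 5 higher and 1 lower adjusted over the list alone; median 1.30, adjusted p = 3.60e-04, adjusted p = 0.236 with an estimated correlation). The lymphatic and sinusoidal receptor Flt4 rose 3.74-fold and the receptor Csf1r 2.81-fold to 25.5 ± 9.04 CPM. Summed per library in plain CPM, monocyte and macrophage markers went from 1390 ± 207 to 855 ± 53.3 CPM, but Vcam1 made up 92.6% of that sum, and without it the others rose from 63.5 ± 5.59 to 102 ± 8.17 CPM. Sinusoidal endothelial markers went from 2140 ± 231 to 1537 ± 84.0 CPM, B cell markers from 654 ± 56.6 to 449 ± 65.0 CPM and Schwann cell markers from 184 ± 13.3 to 231 ± 30.2 CPM (each of these 5 differences exact permutation p = 0.0286, the smallest possible). The last 3 sums did not separate without their most abundant markers Vcam1, Ebf1 and Ncam1 (exact p = 0.429, 0.457 and 0.114). The sums of neutrophil, erythroid, megakaryocyte, dendritic, plasma cell, T and NK cell, arterial and pericyte markers did not separate (exact permutation p = 0.0571 to 0.657), nor did Ptprc (CD45; 3.63 and 4.47 CPM, exact p = 0.571). Without their most abundant markers Fbln5, Notch3 and Xbp1, arterial markers rose from 222 ± 19.0 to 996 ± 513 CPM and pericyte markers from 249 ± 36.3 to 353 ± 27.6 CPM, and plasma cell markers fell from 158 ± 22.3 to 101 ± 15.5 CPM (each exact p = 0.0286). Most of the arterial rise was Mgp, which went from 148 ± 24.0 to 855 ± 446 normalised CPM, with Py230 replicate 1 at 1519. Gja5, the other arterial marker that passed edgeR's test, went from 3.14 ± 1.48 to 18.7 ± 13.7 CPM. Leaving out the most abundant markers was chosen after seeing the data.

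The remaining lists were not called: TGF-beta response (adjusted p = 0.25), immediate-early and stress genes (0.192), unfolded protein response (0.363), cell cycle (0.582), ribosomal proteins (0.582), collagen and matrix (0.582), chondrocyte (0.433), HSC identity (0.454), neutrophil maturation (0.61), basophil-mast-eosinophil (0.639), megakaryocyte-erythroid (0.715), lymphoid and granulocyte-monocyte (both 0.967). Among markers these were megakaryocyte (0.305), Schwann (0.35), sinusoidal (0.383), erythroid (0.582), neutrophil (0.632), dendritic (0.708) and monocyte-macrophage (0.967) markers. B cell, plasma cell, T and NK cell markers and MHC class II genes had under 5 tested members.

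MSC bulk genes higher numbered 324 and MSC bulk genes lower 447 among 16317 tested, and CPM ranges of the groups did not overlap for 1790 genes, where chance gives 2.86%. Higher and lower counts were 147 and 230 without tumour-free replicate 1, 134 and 260 without tumour-free replicate 2, and 181 and 276 without Py230 replicate 2; without tumour-free replicate 3 188 genes rose. At equal depth tumour-free replicate 1 (23139) and Py230 replicate 3 (19597) showed the fewest genes of their groups, and without both, an alternative chosen after seeing the data, 171 genes rose and 305 fell.

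The stromal libraries compare a PyMT with a WT mouse, cell by cell. LepR+ mesenchymal-like cells made up 44.6% of the WT library (977 of 2190 cells, 95% interval 42.5 to 46.7) and 70.3% of the PyMT library (2242 of 3191, 68.6 to 71.8), a difference of 25.6 points. Fibroblast-like cells, led by Pi16, Ccl11 and Dpt, made up 25.5% and 10.8%, a difference of −14.7 points (−17.6 to −11.7). A cluster led by Fmod, Chad and Prg4, which stayed unnamed and is called stromal cluster 1, made up 20.1% (18.5 to 21.9) and 11.5% (10.4 to 12.7). Sinusoidal endothelial-like cells were at 2.51% and 3.76%, an unnamed cluster led by Cd36, Podxl and Flt1 at 4.34% and 1.91%, and osteolineage-like cells at 2.88% and 1.72%. With 1 library per genotype these shares have no replicate check, the sort behind them is not described in the labels, and Clopper-Pearson intervals cover counting error only.

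**Figure D2:**
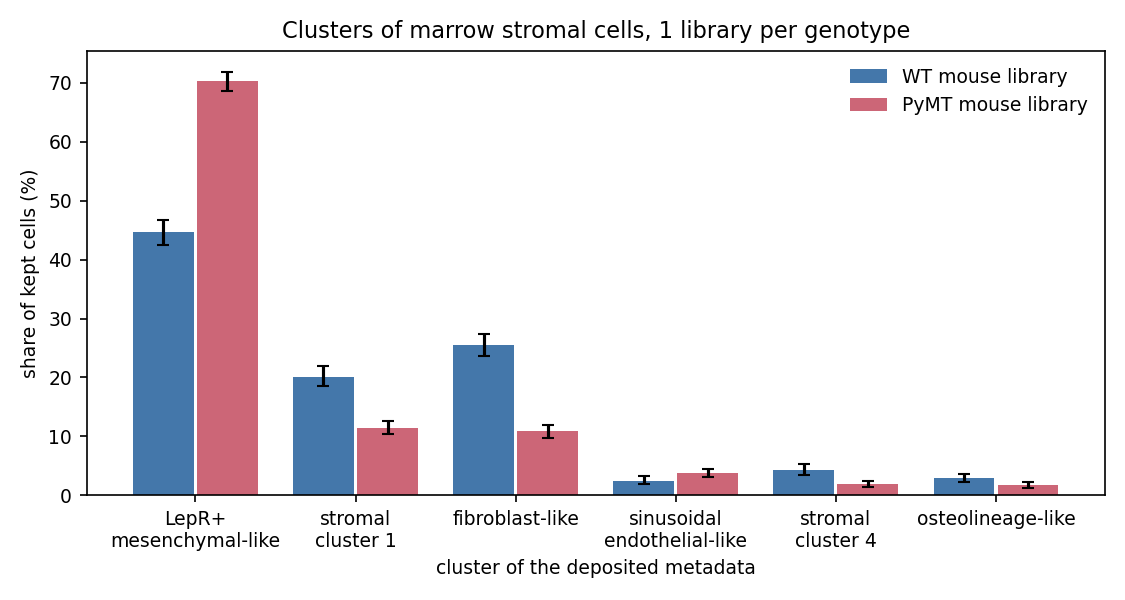
Share of kept stromal cells (%) in each of the 6 clusters of the deposited metadata, for the WT library in blue and the PyMT library in red; whiskers are 95% Clopper-Pearson intervals. LepR+ mesenchymal-like cells were at 44.6% and 70.3%, fibroblast-like cells at 25.5% and 10.8%.

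Within LepR+ cells, Bmp4 was at 332 CPM in the WT and 122 CPM in the PyMT library (log2 ratio −1.44, Poisson interval −1.56 to −1.33) and Adipoq, which also leads this cluster, at 1824 and 713 CPM (log2 ratio −1.36, −1.40 to −1.31). Lpl, Chrdl1 and the cytokine Il34 were likewise lower (log2 ratios −0.85, −0.89 and −1.09), as were Il7 (−0.61), Csf1 (−0.55) and Vcam1 (−0.47). Cxcl12 differed far less than in the bulk comparison, at 20937 and 18614 CPM (−0.17, −0.18 to −0.16), and Angpt1 likewise (−0.18, −0.31 to −0.05); whether the models differ was not tested. Kitl and Lepr were higher in the PyMT library (0.26 each) and Spp1 lower (−0.63). The cytokine Il6 was at 27.5 and 149 CPM (2.44, 2.15 to 2.74). Has2, which makes hyaluronan, was at 2.43 and 28.1 CPM (3.53, 2.59 to 4.67), and the acute-phase gene Serpina3n at 2.97 and 22.9 CPM (2.95, 2.08 to 3.97), beside Rgs5 (2.96), Rgs4 (2.74) and Fgl1 (2.74). A2m (−2.54), Adamdec1 (−2.41) and Adh1 (−2.30) were lower. The beta-globins Hbb-bs (−2.31) and Hbb-bt (−2.13) were lower too, and summed erythroid markers in these cells were at 378 and 103 CPM.

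Of 24 gene lists in LepR+ cells, 17 had a median outside the middle 95% of random lists. Higher were immediate-early and dissociation stress genes (29 of 30 members above 0, median log2 ratio 0.85, random range −0.09 to 0.28), STAT3 targets (21 of 23, 0.60, range −0.11 to 0.31), with Lrg1 (1.77), Osmr (1.06) and Bcl3 (1.03), and NF-kB and cytokine genes (24 of 29, 0.41, range −0.09 to 0.27), with Birc3 (1.13) and Cxcl1 (1.07). Neutrophil maturation (6 of 6, 0.70; neutrophil markers summed to 43.2 and 78.7 CPM), fibroblast (0.40), cholesterol synthesis (0.39), TGF-beta (0.37) and hypoxia genes (0.36) were also higher. The fibroblast median turned to −0.03 when every deposited cell was used, and lay inside the random range at 1500 UMIs per cell (0.28) and with means of per-cell CPM (0.31). Lower were osteolineage (−0.55), adipocyte (−0.43), niche factor (16 of 26 below 0, −0.29, range −0.09 to 0.28), LepR+ identity (−0.17), oxidative phosphorylation (39 of 47 below, −0.31), mitochondrially encoded (−0.28), ribosomal protein (−0.24) and interferon genes (−0.17), the last with Rsad2 at −1.26. Megakaryocyte-erythroid genes (−0.75) include the globins named above and lay inside without doublets (−0.13). With finer clusters LepR+ identity (−0.14) and cholesterol synthesis (0.24) lay inside as well. Of 47 named genes 16 moved outside their intervals in some alternative and 0 changed sign; Serpina3n moved furthest, to 1.42 at 1500 UMIs per cell, and Spp1 lay between −0.85 and −0.39. Cholesterol synthesis and NF-kB genes, which were lower as lists in the bulk MSC, went the other way here. The STAT3 target and immediate-early lists share Fos, Junb and Socs3. Joint clustering at resolution 0.6 gave a group of 30 WT and 1303 PyMT cells. Il6 and the stress gene Dnajb1 were among its leading genes. A difference in dissociation stress between these libraries could therefore not be told apart from a response to the tumour. Chondrocyte (−0.10), unfolded protein response (0.02), HSC identity (0.03), collagen (0.11), lymphoid (0.16), granulocyte-monocyte (0.26) and cell cycle genes (0.29) lay inside.

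**Figure D3:**
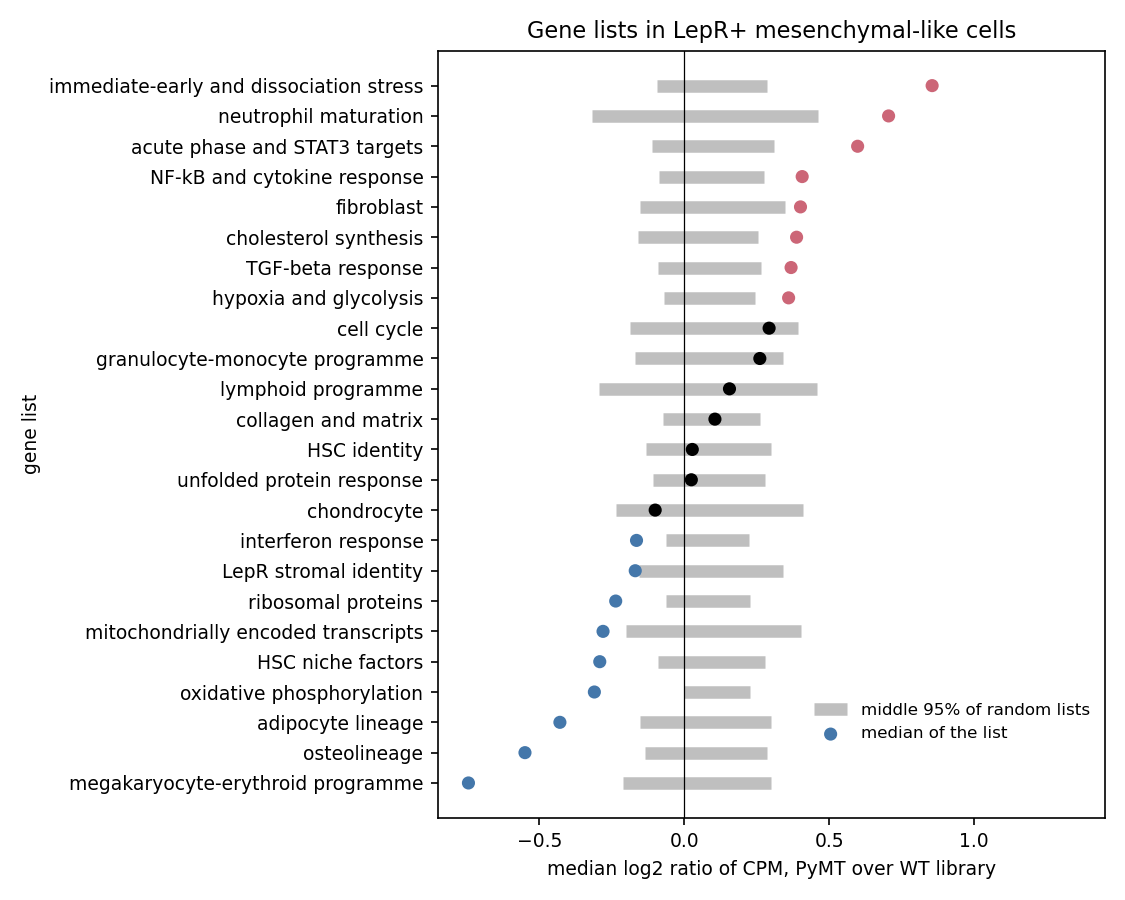
Median log2 ratio of CPM, PyMT over WT library, of each gene list in LepR+ cells (points), over the middle 95% of 10000 random lists matched on expression (grey bars). Red points lie above and blue points below the random range, and black points inside it: immediate-early (0.85) and STAT3 target genes (0.60) lay above, adipocyte (−0.43) and niche factor genes (−0.29) below.

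Other stromal clusters were described in the same way, and differences between clusters were not tested. In fibroblast-like cells Spp1 was at 17.9 and 173 CPM (log2 ratio 3.27, 2.87 to 3.69), Il6 at 31.9 and 208 CPM (2.71), and the chemokine genes Ccl7 (1.97) and Ccl2 (1.87) were higher. NF-kB genes (27 of 27 above 0, median 0.75), immediate-early genes (0.90) and STAT3 targets (0.71) lay above their random ranges, and the acute-phase gene Saa3 had 2 UMIs in the WT and 69 in the PyMT library (5.77, 3.87 to 8.85). Neutrophil markers summed to 6.07 and 31.3 CPM in these cells. As in LepR+ cells, dissociation stress could not be told apart from a response to the tumour. The chaperone genes Sdf2l1 (−1.81) and Manf (−1.22) were lower, with unfolded protein response genes at −0.22. In stromal cluster 1, Msmp had 0 UMIs in the WT library and 637 in the PyMT library (95% lower limit of the log2 ratio 7.71), and Col10a1, the collagen of hypertrophic cartilage, had 1 and 211 UMIs (log2 ratio 8.01, 5.51 to 13.3). Chondrocyte genes (1.41), osteolineage genes (0.84) and interferon genes (0.79) had medians above their random ranges there, and Spp1 was at 970 and 3444 CPM. Neutrophil markers summed to 9.15 and 21.7 CPM in that cluster. Chad, which leads that cluster, was itself at 2629 and 736 CPM. Joint clustering, looked at here only after seeing these values, split most of the cluster into parts led by Chad (352 WT and 236 PyMT cells), Spp1 (46 and 60) and F13a1 (25 and 32). Spp1 was lower in the part led by Chad (811 and 603 CPM) and higher in the part that it leads (3722 and 18471 CPM), which held all 211 Col10a1 UMIs of the PyMT library, while 634 of its 637 Msmp UMIs lay in the part led by Chad, where Chad was lower too (log2 ratio −1.46). Values of the whole cluster therefore mix parts that differ, and the parts rest on the same genes.

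Among HSPC, cells resembling granulocyte-monocyte progenitors (GMP-like; led by Elane, Ms4a3 and Mpo) made up 6.49% (Clopper-Pearson interval 5.69 to 7.37) and 1.76% (1.26 to 2.40) of cells in the WT mice and 17.3% (16.1 to 18.6) and 7.83% (7.14 to 8.56) in the PyMT mice. Means were 4.13% ± 3.34 and 12.6% ± 6.69 (SD, n = 2), and the exact permutation p of 0.333 is the smallest that 2 mice against 2 allow. In edgeR's test of cell numbers per cluster 0 of 11 clusters passed: the log2 change of GMP-like cells was 1.59 (adjusted p = 0.24), and adjusted p was 0.0733 at the lowest, in clusters 1, 6 and 9. Among HSPC class shares, this difference of 8.44 points was 7.93 when cells were clustered without the 304 genes that differed, 3.70 without PyMT mouse 1 and 13.2 without PyMT mouse 2. Lymphoid-primed-like cells (clusters 1 and 8, led by Dntt and Wfdc17) made up 14.5% and 15.4% in WT and 22.1% and 19.97% in PyMT mice (exact p = 0.333). Their mean share rose in cluster 1, from 9.46% to 18.2% (exact p = 0.333), and fell in cluster 8, from 5.49% to 2.81% (exact p = 0.667). No counterpart of cluster 8 was left in any of 3 other clusterings. There the lymphoid-primed-like shares, WT mice first, were 5.61%, 7.92%, 15.3% and 9.79% without the genes that differed, 9.26%, 12.2%, 11.9% and 11.02% with library-centred components, and 5.77%, 8.61%, 6.65% and 6.34% at 2000 UMIs per cell, so the order held in 1 of the 3. PyMT mouse 2 had fewer UMIs per cell than the other mice (median 4257 against 6644 to 7149). GMP-like cells per lymphoid-primed-like cell numbered 0.449 and 0.114 in WT and 0.783 and 0.392 in PyMT mice, a 2.45-fold difference of geometric means (log2 1.29, exact p = 0.667). The log2 difference of this HSPC myeloid to lymphoid ratio was 0.30 without WT mouse 2 and 2.28 without WT mouse 1. Clustered without the genes that differed, the ratios were 1.24 and 0.274 in WT and 1.09 and 0.842 in PyMT mice, so WT mouse 1 lay above both PyMT mice. HSC-like cells were at 21.8% and 22.8% in WT and 15.8% and 27.5% in PyMT mice (exact p = 1.0). The gate that set these shares is not given in the labels.

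**Figure D4:**
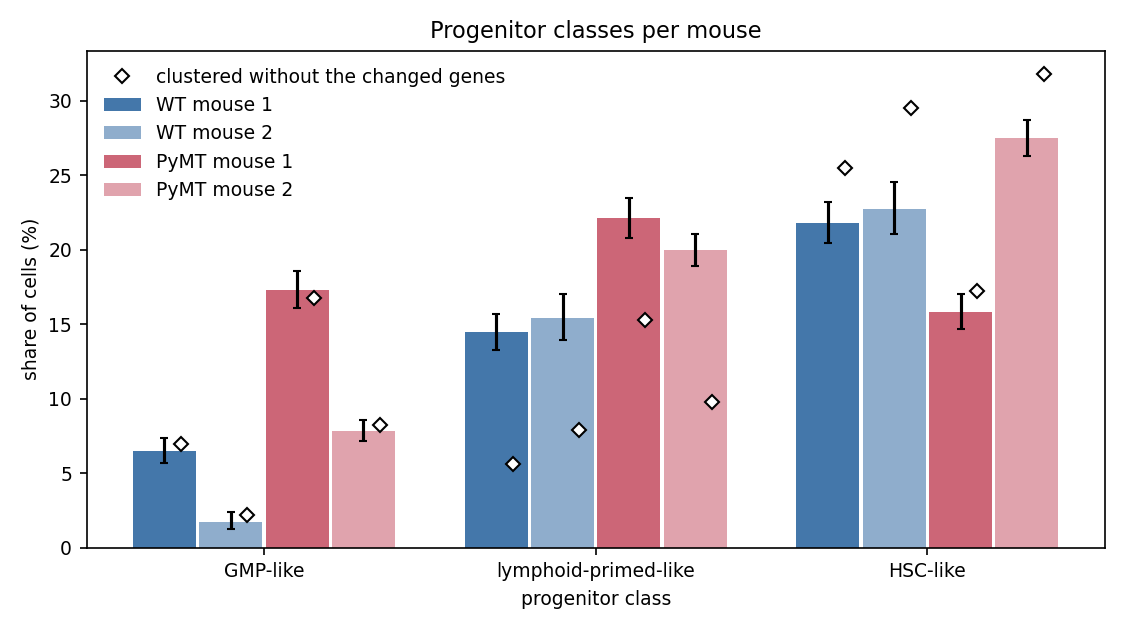
Share of cells (%) in 3 progenitor classes of each of 4 mice, WT in blue and PyMT in red; whiskers are 95% Clopper-Pearson intervals and diamonds give the share when cells were clustered without the changed genes. GMP-like shares were 6.49% and 1.76% in WT and 17.3% and 7.83% in PyMT mice, and HSC-like shares overlapped.

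Over all HSPC of a mouse, Socs3, the feedback inhibitor induced by STAT3, rose from 9.01 ± 1.98 to 56.7 ± 6.86 CPM (SD, n = 2; log2 change 2.64, SE 0.16, adjusted p = 5.41e-04). Its relative Socs1 rose 2.33-fold, the NF-kB cofactor Bcl3 2.08-fold, the myeloid transcription factor Cebpb 2.60-fold and the AP-1 member Junb 2.17-fold. Cd200r4, a CD200 receptor family gene, rose 5.72-fold, and Cox6a2 (2.10-fold), Tpm4 (1.90-fold) and Nop16 (1.59-fold) also rose. The platelet chemokine Pf4 fell from 408 ± 27.3 to 122 ± 11.8 CPM (log2 change −1.75, SE 0.11, adjusted p = 3.07e-04), beside the water channel Aqp1 (2.62-fold lower), the platelet genes Gp9 (1.75-fold) and Treml1 (2.37-fold), and Mfsd2b, Sdpr and Ndrg1. Cdk5rap1, a modifier of transfer RNA, fell from 40.7 ± 1.49 to 10.9 ± 2.24 CPM, and whether this comes from the mouse strain stays open. Ifitm1 (2.83-fold higher) was not called without PyMT mouse 1 (adjusted p = 0.235) or PyMT mouse 2 (0.135), nor was the erythroid gene Car1 (3.91-fold lower; 0.194 and 0.169). Socs3 (ENSMUSG00000053113) lies on chromosome 11 from 117966079 to 117970047 on the minus strand and Pf4 on chromosome 5 from 90772435 to 90773383 on the plus strand.

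The neutrophil granule genes Mpo (2199 ± 1217 and 4202 ± 621 CPM, log2 change 0.93, SE 0.48) and Elane (564 ± 436 and 1442 ± 490 CPM, 1.35, SE 0.87) did not pass the test (adjusted p = 0.36 and 0.482), but both did without WT mouse 1 (1.6e-06 and 0.001). Irf8, a monocyte and dendritic cell regulator, did not pass either (log2 change 0.65, adjusted p = 0.383, and log2 change 1.10 without WT mouse 1). Neither did Cebpa (log2 change 0.29, adjusted p = 0.653, and log2 change 0.63 without PyMT mouse 2) nor Dntt (0.29, adjusted p = 0.429, and 0.59 without WT mouse 2). The lymphoid genes Flt3 and Il7r did not pass (0.666 and 0.897). Of stem cell genes, Procr (0.803), Hlf (log2 change −0.86, adjusted p = 0.0912) and Mecom (−0.50, 0.197) did not pass. The log2 change of Hlf was −1.06 without WT mouse 1 and −0.64 without WT mouse 2. That of Mecom was −0.84 without PyMT mouse 2. The erythroid regulators Gata1 (log2 change −0.61, adjusted p = 0.0737) and Klf1 (−0.69, 0.0656) did not pass. Their log2 changes were −0.79 and −0.78 without WT mouse 2, and −0.74 and −0.53 without PyMT mouse 2. That of Klf1 was −0.88 without PyMT mouse 1.

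STAT3 target genes rose as a list (7 of 20, 10 adjusted over the list alone; median log2 change 0.90, adjusted p = 4.28e-21, adjusted p = 0.22 with an estimated correlation). Granulocyte-monocyte genes (median 0.65, adjusted p = 1.44e-06, adjusted p = 0.535 with an estimated correlation) and neutrophil maturation genes (0.72, adjusted p = 1.23e-04, 0.499) were higher as lists, with 1 of 29 and 1 of 15 members passing (3 and 2 adjusted over the list alone). The member of the latter was the membrane protein gene Ifitm6. That of the former, Mgst1, was lost without WT mouse 2 (adjusted p = 0.206). Megakaryocyte-erythroid genes fell (8 of 28, 17 adjusted over the list alone; median −0.72, adjusted p = 1.17e-21, adjusted p = 0.491 with an estimated correlation). Clusters 6 and 9, which Pf4 and Gata1 help to lead, were also smaller when cells were clustered without the genes that differed: 11.9% and 9.73% in WT and 6.39% and 5.87% in PyMT mice for cluster 6, and 4.97%, 4.57%, 2.78% and 2.84% for cluster 9. At 2000 UMIs per cell cluster 9 had no counterpart, and cluster 6 held 12.2%, 10.9%, 5.79% and 6.16%. The fall over all cells therefore did not separate a change of cell mix from one within cells. HSC identity genes were lower as a list (median −0.37, adjusted p = 6.55e-04, 0.499 with an estimated correlation) but moved both ways. Ly6a (Sca-1) and Ifitm1 were among 3 higher members, and the transcription factors Gata2 and Meis1 were the 2 lower ones; 3 rose and 10 fell adjusted over the list alone.

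Oxidative phosphorylation genes were higher (3 of 47, 19 adjusted over the list alone; median 0.25, adjusted p = 3.26e-12, 0.499 with an estimated correlation), with the ATP synthase gene Atp5o at 1.64-fold; Cycs and Uqcrq were lost without WT mouse 2 (0.107 and 0.24). Unfolded protein response genes were higher (2 of 24, 14 adjusted over the list alone; median 0.42, adjusted p = 1.66e-09, 0.491), with the regulator Xbp1 at 1.61-fold; Pdia6 was lost without WT mouse 2 (0.102). Immediate-early genes were higher (2 of 27, 6 higher and 2 lower adjusted over the list alone; median 0.43, adjusted p = 1.34e-06, 0.491) and niche factor genes lower (1 of 16, 7 adjusted over the list alone; adjusted p = 8.88e-04, 0.491). The 2 immediate-early genes that passed, Socs3 and Junb, are also on the STAT3 target list. Weaker calls of higher lists were interferon (adjusted p = 0.0133; 0.105 without WT mouse 1, 0.664 without PyMT mouse 2), hypoxia (0.0147; 0.165 without PyMT mouse 1) and cell cycle genes (0.0273; 0.0908 without WT mouse 1, 0.252 without PyMT mouse 1), all lost with an estimated correlation (adjusted p = 0.491 to 0.562). Not called were NF-kB (0.056), TGF-beta (0.0994), mitochondrially encoded (0.108), LepR+ identity (0.179), cholesterol synthesis and MHC class II (both 0.221), fibroblast (0.255), chondrocyte (0.30), osteolineage (0.303), adipocyte (0.438), lymphoid (0.502), collagen (0.656) and basophil-mast-eosinophil genes (0.694).

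Over all cells, HSPC summed genes higher numbered 100 and HSPC summed genes lower 65 among 11759 tested, and DESeq2 called 467 and 161. With a single mouse left in one group, assumed to vary like those of the other, the counts grew to 347 and 206 without WT mouse 1, 716 and 390 without PyMT mouse 1, and 1135 and 797 without PyMT mouse 2; without WT mouse 2, 19 lists in place of 12 were called.

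Within clusters the STAT3 pattern recurred. STAT3 targets were higher in 9 of 9 clusters tested (medians 0.64 to 0.98, adjusted p = 3.17e-36 to 7.40e-13; adjusted p = 0.12 to 0.329 with an estimated correlation). Unfolded protein response and immediate-early genes were higher in 9 of 9 as well (medians 0.19 to 0.38 and 0.09 to 0.66), oxidative phosphorylation in 8, NF-kB and LepR+ identity lists in 7, and granulocyte-monocyte and interferon genes in 6. The LepR+ identity list was made for stromal cells. Over all HSPC 11 of its 24 genes were tested, and it was not called (camera, adjusted p = 0.179). Mitochondrially encoded transcripts were lower in 9 of 9 (medians −0.19 to −0.09), niche factors in 5 of 7, and megakaryocyte-erythroid genes in 3. With an estimated correlation 0 of these camera calls held (adjusted p = 0.12 at the lowest). Junb rose in 9 of 9 clusters (log2 changes 0.78 to 1.49), Socs3 in 7 of 8 (1.66 to 3.08), Cebpb in 7 of 9 (0.57 to 1.53) and the kinase gene Pim1 in 7 of 9, whereas Cdk5rap1 fell in 7 of 9 (median −1.80). Both the STAT3 target list and the immediate-early list hold Junb and Socs3. In HSC-like cells Junb rose from 320.2 ± 26.4 to 896 ± 32.9 CPM (log2 change 1.49, SE 0.10), Cebpb 2.68-fold and Cd200r4 12.2-fold, while Pf4 and the stem cell gene Hlf fell (log2 changes −1.60 and −0.75; Hlf from 276 ± 22.3 to 164 ± 1.69 CPM).

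**Figure D5:**
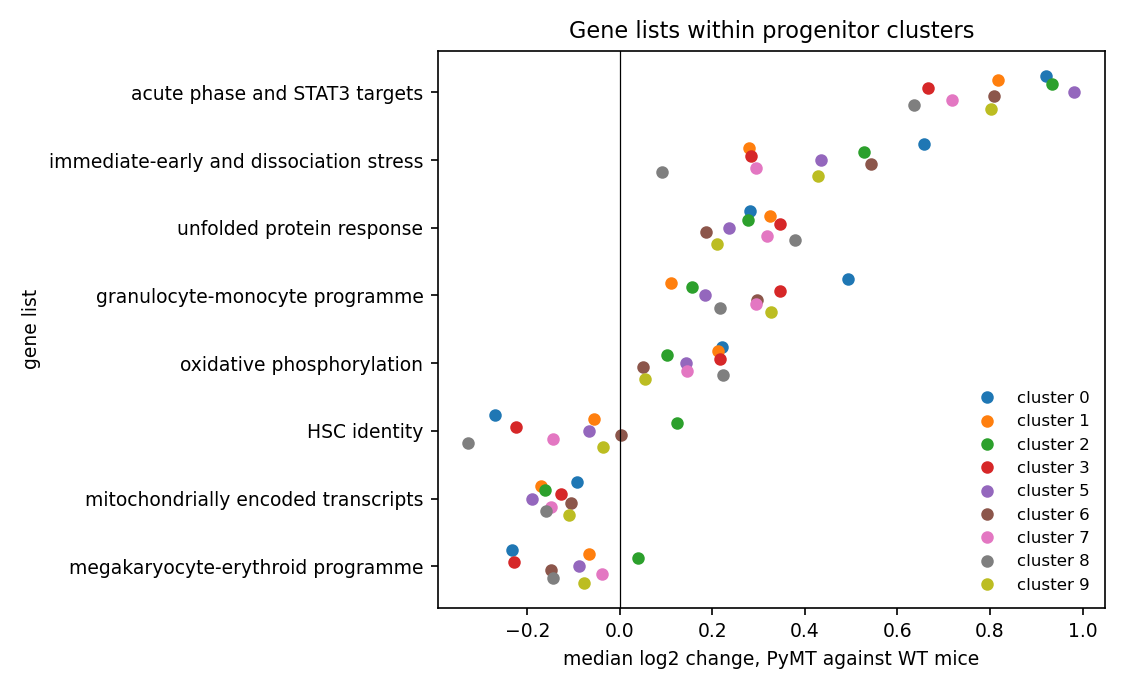
Median log2 change, PyMT against WT mice, of 8 gene lists in each of 9 HSPC clusters (points coloured by cluster; 2 mice per genotype). STAT3 target medians lay between 0.64 and 0.98 in every cluster, and those of mitochondrially encoded transcripts between −0.19 and −0.09.

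HSPC class genes changed numbered 374 calls over the 9 clusters, for 210 distinct genes, from 3 in cluster 9 to 96 in cluster 3; GMP-like cells were not tested, because 1 WT mouse had 39 of them. That number was 922 without WT mouse 1, 2822 without PyMT mouse 1, 1743 without PyMT mouse 2 and 963 without a filter on low counts.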

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

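The tests of a changed mix of clusters and of a lower share of LepR+ cells were chosen only after the results were seen.

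STAT3 target genes were higher in HSPC of PyMT mice, in 9 of 9 clusters tested by camera, which argues against a changed mix of clusters as the whole cause, although with an estimated correlation 0 of 9 calls held (adjusted p = 0.12 to 0.329). RNA from neutrophils is argued against too: in HSC-like cells the neutrophil markers rose by 17.9 CPM and the STAT3 targets by 2065 CPM, a ratio of 0.0087. On dissociation stress, genes of the STAT3 list alone rose by a median of 0.70 and genes of the immediate-early list alone by 0.30. That difference of 0.4051 was reached by 0.32% of 10000 reassignments, which take genes and not mice as units. Immediate-early genes were themselves called higher in 9 of 9 clusters, so this test cannot exclude stress. A response of HSPC to cytokines in PyMT mice is a hypothesis that stays open, as does any other difference between these mice, such as strain or handling.

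Niche factor genes were lower in MSC of mice with Py230 tumours. Of the 14 called lower, 14 stayed so with the number of genes detected as a covariate. That number did not separate the groups (29290 and 29846 at equal depth, exact permutation p = 0.914). The covariate could therefore hardly have removed the calls, and groups alike in library complexity give that explanation little support. Cxcl12 fell more than Lepr and Kitl, whose mean log2 over Cxcl12 was higher by 0.769 in the tumour group (exact permutation p = 0.0286). The genes were picked after their changes were seen, so this p-value adds no further evidence. Of 24 LepR+ identity genes 8 fell over all genes, the niche factors Cxcl12 and Gas6 among them, and 0 rose. A lower share of LepR+ cells therefore stays open. As for chance, 1 of 35 splits of the 8 libraries, the real one, gave as many as 324 higher or 447 lower genes (edgeR). The highest other value was 0 for each. No smaller share is possible with 35 splits, and all other splits mix the groups, so chance is argued against but not excluded. For the 13 lists called, chance stays open, because 5 of 35 splits gave as many, the highest other 19. A response of the niche to the tumour, a change in the kinds of LepR+ cells sorted, and differences between animals stay open.

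Cdk5rap1 was the 1 gene lower in at least 5 HSPC clusters. A strain difference between PyMT and WT mice cannot be told apart from an effect of the tumour: in LepR+ stromal cells the log2 ratio was 0.3146, but it rests on 1 gene with 15 and 54 UMIs, and its interval, −0.50 to 1.28, is too wide to exclude a lower level there. In MSC of mice with Py230 tumours the log2 change was 0.09.

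Single MSC libraries lay far from the other 3 of their group for 9 of 160 groups of values, and chance gives about 1 in 20. Gap over range was 0.843 for Mmp11 in tumour-free replicate 3 (24.0 CPM, others 27.6 to 28.3), 0.877 for Gas6 in tumour-free replicate 4 (875 CPM, others 1326 to 1389), 0.858 for Gsn in tumour-free replicate 3 (184 CPM, others 123 to 131) and 0.858 for Irgm1 in tumour-free replicate 4 (88.2 CPM, others 209 to 229). It was 0.86 for Atp5g3 in tumour-free replicate 2 (25.3 CPM, others 27.8 to 28.2) and 0.856 for Ly6a in tumour-free replicate 3 (2.27 CPM, others up to 1.04). In the tumour group it was 0.854 for Mgp in replicate 1 (1519 CPM, others 579 to 716), 0.85 for Stab1 in replicate 4 (28.1 CPM, others 18.3 to 19.8) and 0.906 for F13a1 in replicate 4 (8.84 CPM, others 3.97 to 4.42).

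The PyMT change of 8 of 23 lists differed between lymphoid-primed-like cluster 1 and HSC-like cells, which come from the same 4 mice. The median difference, lymphoid-primed-like minus HSC-like, was −0.25 for fibroblast (camera, adjusted p = 0.0116), −0.38 for STAT3 target (1.13e-05), −0.41 for immediate-early (2.94e-10), −0.32 for granulocyte-monocyte (2.60e-10), −0.49 for neutrophil maturation (0.0224) and −0.42 for lymphoid genes (2.22e-04). It was 0.10 for HSC identity (0.00275) and 0.16 for megakaryocyte-erythroid genes (0.0099). These are medians of the differences per gene, not differences of the cluster medians. In HSC-like and lymphoid-primed-like cells the STAT3 target medians were 0.92 and 0.82, and the immediate-early medians 0.66 and 0.28. With an estimated correlation 0 of the 8 held (adjusted p = 0.466 to 0.675). Of single genes, 51 of 10340 differed.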

How the results depend on the processing

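The tests that left out the libraries with the fewest genes, added genes detected as a covariate, centred libraries, clustered without the changed genes, thinned HSPC to 2000 UMIs, clustered stroma at resolution 0.6 or left the most abundant marker out of sums were chosen only after the data were seen.

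MSC bulk genes higher and MSC bulk genes lower (324 and 447) numbered 176 and 237 with the replicate number as a block. The numbers do not pair the libraries: correlations of same-numbered libraries were −0.39, −0.13, −0.20 and 0.02. Only tumour-free replicate 4 correlated best with its own number in the other group. Without the libraries with the fewest genes 171 rose, and leaving out single libraries gave 134 to 304 higher and 230 to 426 lower. Of 13 MSC bulk gene lists called, 1 held with an estimated correlation and fry called 4; leaving out single libraries gave 10 to 14. Over all alternatives 1038 of 1140 values of named MSC genes kept their direction and side of the threshold, 81 lost and 21 gained a call, and 0 reversed; for lists these were 486 of 535, 41, 8 and 0. With the most abundant marker left out, MSC marker sum monocyte and macrophage reversed from −535 to 38.6 CPM and MSC marker sum B cell from −205 to 3.83 CPM; of the other 10 sums 2 lost and 3 gained a separation.

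In the stroma LepR+ list fibroblast reversed to −0.029 with every deposited cell; 136 of 143 list values kept their place, 5 lost and 1 gained a call, and 255 of 282 gene values kept theirs while 27 moved beyond their interval, and shares kept theirs in 24 of 24. In the other clusterings each new cluster took the name of the deposited cluster that held most of its cells. Shares that stayed alike there are therefore a weak check of the clustering.

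HSPC summed genes higher and HSPC summed genes lower (100 and 65) numbered 467 and 161 with DESeq2, and 100 to 1135 and 84 to 797 with single mice left out. HSPC class genes changed (374) numbered 963 without a filter and 317 to 2822 with single mice left out. Of 12 HSPC gene lists called by camera, 0 held with an estimated correlation (2 of 25 had an unadjusted p under 0.05); with single mice left out 12 to 19 were called. The HSPC list basophil-mast-eosinophil programme reversed, with adjusted p between 0.00754 and 0.664 over the mice left out. The GMP-like difference among HSPC class shares ran from 3.70 to 13.2 points and the log2 HSPC myeloid to lymphoid ratio from 0.30 to 2.28. Of named HSPC genes 325 of 392 values kept their side, 8 lost and 59 gained a call. For these changes, and those of MSC and stroma above, the cause was not tested.

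No stricter cell filter was run for HSPC, since it removed 0 cells. A mouse left alone in its group was assumed to vary like the other group. With 4301375 to 9811251 reads per MSC library and 2 mice per HSPC group, small changes are missed, as the simulated recoveries show.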

Other observations

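Genes that changed in MSC of mice with Py230 tumours were also followed in LepR+ cells of the stromal libraries, which come from other mice and another tumour model. Of the 324 genes that rose, 295 were measured there, and 263 of them (89.2%) were higher in the PyMT library, against 57.1% of all genes; their median log2 ratio was 0.52, where random lists gave 0.03 to 0.13. Of the 447 that fell, 417 were measured and 296 (71.0%) were lower, against 42.9% of all genes, with a median of −0.28 (random lists 0.04 to 0.13). With 1 library per genotype, this overlap describes these 2 libraries.

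Within HSPC clusters other genes changed as well. In lymphoid-primed-like cluster 8 the endolysosomal gene Pld4 rose from 11.9 ± 3.42 to 77.8 ± 13.9 CPM (log2 change 2.65, SE 0.37), while Hlf (−1.70) and the stem cell factor receptor Kit (−1.09) fell. That cluster had no counterpart in the other clusterings and held as few as 64 cells and 249063 UMIs in a library. Whether these changes reflect which cells fell into it was not tested. Kit was called lower in 4 of 9 clusters (median −0.66), as were the MHC class I genes H2-Q7 (−0.60) and H2-T23. Wfdc17, a whey acidic protein family member, rose in clusters 5 and 7 (log2 changes 1.76 and 1.51), and the serpin gene Serpina3g in cluster 6 (1.11), where the mast cell protease gene Cpa3 fell (−1.12). In cluster 3, led by mitotic genes, Angpt1 fell (−0.95).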
